A study of Mus musculus with 42 samples.

How the data were processed

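The gene counts of all 42 libraries were taken as deposited, in 1 count table made by the authors. Per the submitters' processing notes, the reads were aligned to the mouse genome mm10 with STAR 2.7.3a and counted per gene with featureCounts before deposit. Library construction followed the ultra-low-input protocol of the Immunological Genome Project. Fresh cells were sorted into lysis buffer at 1000 cells per library, culture wells were lysed directly, and the floating cells entered as 2 ng of purified RNA. The notes do not give the annotation release, the strand setting, or how reads shared between near-identical genes were counted. Levels of H2-Q10, H2-T23, Serpina3n, Gbp10 and the predicted genes, which have close copies in the genome, are uncertain for that reason.

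The table held 55011 genes, of which 43853 had at least 1 count, and 52936 symbols were also in GENCODE M21, which was used for positions, transcript lengths and GC content. All values were whole numbers, and every column belonged to 1 sample. No library was left out.

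Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood (QL) F test with robust dispersion estimates. Libraries were scaled with TMM factors, and genes were kept by the default filter of edgeR at a minimum count of 10. Each experiment was fitted alone: the fresh and transferred cells together, the fresh and adipogenic cells together, and the floating cells, the Treg cultures, the OSM cultures and the Treg cells each by themselves. Both differences between responses were contrasts of 4 groups in 1 fit. Adjusted p is from Benjamini-Hochberg (BH) over all genes tested in a comparison, all tests were two-sided, and a gene was called at adjusted p under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. The groups, the 14 comparisons, the 31 gene lists, the thresholds and the alternatives were chosen before the data were examined.

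The lists held 567 distinct genes, of which 3 were absent from the table. They cover the adipocyte program, lipid synthesis, lipolysis, thermogenic genes, oxidative phosphorylation, glycolysis and hypoxia, DPP4+ progenitors, committed preadipocytes, F3+ regulatory stromal cells, anti-adipogenic regulators, matrix, proliferation, the OSM-STAT3 response, both interferon responses, inflammatory genes and dissociation stress. Others cover Treg core, VAT Treg, effector T cell and resting T cell genes, and markers of macrophages, neutrophils, T and NK cells, B cells, endothelial, mesothelial, pericyte, fibroblast and erythrocyte cells and of sex. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with BH over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Sets of genes called in 1 comparison and changed more than 2-fold were tested in others that share no library with it.

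Genes are named by rule. Osm and Foxp3 were always given for the Treg cells, Pparg, Adipoq, Fabp4, Dpp4, Pi16 and Icam1 for stromal cells and adipocytes, and Osmr, Il6st and Socs3 for the cultures. Further genes were list members among the smallest adjusted p of a comparison, or the largest rises and falls among called genes that reached 20 CPM in a group and separated the groups in every library, predicted genes apart. A gene with 0 counts over a group is given a floor of 3 counts over that group, the 95% bound of counting.

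Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, the replicate number as a block, another set of groups in the fit, and every library left out in turn. Chosen after the data were seen were a block with crossed replicate numbers for the floating cells, and list counts without DTR+ replicate 3 and without KO replicate 2. Regroupings of the libraries were used to see how many genes other splits call. Simulated counts with known changes were run through the same steps for every comparison.

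Sequence reads and the altered Osm exons were not analysed here, and other data sets were not used here. Apart from the difference between the OSM and the Treg response, comparisons across experiments were not tested because preparation and depth differ. Examples are floating cells against cultures and Treg cells against stromal cells. Depth also differed between the OSM and the Treg cultures, and depth and preparation between fresh cells and adipogenic cultures, which were compared. The labels do not give a replicate 1 of the floating cells, the sorting gates of VmSC4 and VmSC5, or the Cre line of the Osm mice.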

Results

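Poly(A) RNA was sequenced in 42 mouse libraries that fall into 15 groups, all from visceral adipose tissue (VAT) or cells cultured from it. Stromal cells of the populations labelled VmSC4 and VmSC5 were sequenced fresh from the sorter (n = 3 each), after 8 days of adipogenic culture (n = 3 each) and after transfer into recipient mice, as VmSC4-derived VmSC4 (n = 3), VmSC4-derived VmSC5 (n = 3) and VmSC5-derived VmSC5 (n = 2). Floating cells labelled adipocyte came from Foxp3-DTR+ mice, in which diphtheria toxin removes regulatory T (Treg) cells, and from toxin-treated DTR- littermates (n = 2 each). VmSC5 in adipogenic medium were cultured with or without Treg (n = 3 each), and with oncostatin M (OSM) at 10 ng/mL or PBS (n = 3 each). The sample titles say only with or without Treg, while the series text describes conditioned medium of VAT Treg cells. The last 2 groups were Treg cells labelled Osm wild type (WT) and Osm knockout (KO, genotype OSMf/f; n = 3 each).

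Total counts ran from 8527769 to 12514783 per library in the fresh stromal cells, from 1841664 to 2606360 in the adipogenic cultures, from 1967123 to 5044946 in the transferred cells and from 5932453 to 7490677 in the floating cells. They ran from 4648878 to 7933682 in the cultures with and without Treg, from 1072147 to 2078534 in the OSM and PBS cultures and from 1507163 to 4438234 in the Treg cells. Levels are in CPM, counts scaled to the total of the library, as mean ± SD over the libraries of a group, and fold changes are log2 values ± SE from edgeR. Counts of list genes are over all genes tested, and the count adjusted over the list alone is given where it differs. The labels do not say whether replicates were separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Intervals and floors cover counting error only.

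The Treg libraries addressed what changes in VAT Treg cells that carry the altered Osm gene. Osm encodes oncostatin M and lies on chromosome 11 from 4236420 to 4241026 in GRCm38. It stood at 29.1, 28.4 and 34.1 CPM in the 3 WT libraries and at 9.83, 14.6 and 7.76 CPM in the 3 KO libraries, a mean of 30.5 ± 3.09 against 10.7 ± 3.5. Every KO library lay below every WT library, and Osm reads were left in all 3. The log2 fold change of Osm was -1.51 ± 0.35, with an adjusted p of 0.271 in edgeR and 0.0129 in DESeq2, and it passed in edgeR without the low-count filter (0.0213) or without KO replicate 1 (0.0389). Foxp3, the transcription factor that defines Treg cells, was at 276 ± 108 CPM in KO and 314 ± 18.6 in WT (edgeR adjusted p = 0.906). KO replicate 1 had the lowest Foxp3 level at 154 CPM. Ikzf2, which encodes the Treg factor Helios, was at 725 ± 149 and 841 ± 69.5 CPM (edgeR adjusted p = 0.780).

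Of 11416 genes tested, edgeR called 1 higher and 5 lower in KO Treg cells, and 1158 had an unadjusted p under 0.05. DESeq2 called 62. Lpcat2, an acyltransferase of phospholipid remodelling, was the higher gene, at 52.5 ± 11.6 against 13.5 ± 2.61 CPM (log2 fold change 1.99 ± 0.30, edgeR adjusted p = 0.0445). The 5 lower genes were predicted genes, named here after their values were seen: Gm10717, Gm10800, Gm10801, Gm21738 and Gm6969. Gm10800 alone took 1.28% to 1.50% of the counts of the WT libraries and 0.446% to 0.633% of the KO libraries. Its share also differed between experiments, at 0% to 0.0002% in the floating cells and 1.13% to 1.73% in the OSM and PBS cultures. Whether these 5 calls are separate changes or 1 technical difference between the libraries was not tested. The lists of Treg core genes (19 tested), VAT Treg genes (27), effector T cell genes (12), resting T cell genes (13) and T and NK cell genes (15) held 0 called genes over all genes tested, and adjusted over the list alone only the VAT Treg list held 1, Osm itself. Without KO replicate 2, which had 16756 genes detected against 21202 to 24287 in the other Treg libraries, these lists again held 0 called genes, and adjusted over the list alone Osm fell and Nt5e, a Treg core gene named here after its values were seen, rose. The count of calls was 0 without WT replicate 1 or 3, 1 without WT replicate 2 or KO replicate 3, and 586 without KO replicate 1. The lists were not counted without KO replicate 1, so whether they hold without it was not tested. The Lpcat2 call ended without WT replicate 1, 2 or 3 and without KO replicate 2 or 3, with adjusted p values from 0.111 to 0.505. On simulated data of this comparison, 29% of genes changed 2-fold and 74% of those changed 4-fold were recovered, and 10.4% of the calls were false. The simulated data held 200 changed genes, so that share of false calls does not carry over to the calls in the real libraries.

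**Figure D1:**
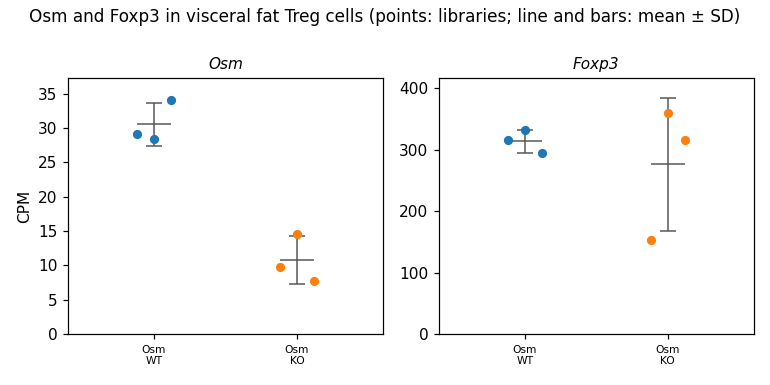
Osm and Foxp3 in Treg cells of VAT, in CPM on a linear axis from 0, with 1 point per library and the mean ± SD for WT and KO (n = 3 each). Osm lay between 28.4 and 34.1 CPM in WT and between 7.76 and 14.6 CPM in KO.

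Fresh VmSC5 and fresh VmSC4 were compared to ask how the populations differ before transfer or culture. Fresh VmSC5 carried more of the transcripts of DPP4+ interstitial progenitors, the adipose stem-like cells of the tissue's connective sheets. Dpp4, the peptidase that names them, was at 17.1 ± 1.14 CPM in VmSC5 and 2.09 ± 0.634 in VmSC4 (log2 fold change 3.11 ± 0.21, edgeR adjusted p = 3.6e-10). Pi16, a secreted protein of universal fibroblasts, was at 141 ± 43.9 against 42.8 ± 11.4 CPM (1.82 ± 0.22, edgeR adjusted p = 6e-05), and Ackr3, a chemokine scavenging receptor, at 226 ± 9.99 against 63.3 ± 18.3 CPM. The largest rise was that of Thy1, the surface glycoprotein CD90, at 51.4 ± 4.93 against 0.813 ± 0.196 CPM (6.03 ± 0.25, edgeR adjusted p = 6.8e-15). Of 20 progenitor genes tested, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.17 and a camera adjusted p of 1.2e-20 (adjusted p = 0.00102 with an estimated correlation).

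Matrix genes also leaned toward fresh VmSC5, with 15 of 30 higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 5.1e-07, adjusted p = 0.219 with an estimated correlation). Fn1, which encodes fibronectin, led them at 2563 ± 141 against 1468 ± 78.2 CPM. Aldh1a7, an aldehyde dehydrogenase, had the largest fall, at 0.643 ± 0.373 CPM in VmSC5 and 41.6 ± 14.5 in VmSC4 (-5.88 ± 0.50). Genes of F3+ regulatory stromal cells, which restrain adipogenesis, had 4 of 12 lower in VmSC5 and 0 higher (5 and 0 adjusted over the list alone), among them Gas6, a growth factor, at 476 ± 67.5 against 871 ± 98.5 CPM. Icam1, an adhesion molecule of committed preadipocytes, was higher in VmSC5 by 0.67 ± 0.13 (edgeR adjusted p = 0.000819), and its list had 5 members of 21 higher and 4 lower (8 and 5 adjusted over the list alone). Pparg, the master regulator of adipogenesis, stood at 18.3 ± 7.1 CPM in VmSC5 and 19.1 ± 1.99 in VmSC4 (edgeR adjusted p = 0.970), and the fatty acid carrier Fabp4 at 87.1 ± 9.45 and 126 ± 26.0 (edgeR adjusted p = 0.288). In all, 1034 genes were higher and 1532 lower in VmSC5 among 13947 tested, of which 257 and 608 differed more than 2-fold. Of 9 endothelial genes 3 were lower and 1 higher in VmSC5 (median -0.66, camera adjusted p = 0.454, adjusted p = 0.731 with an estimated correlation), and of 6 macrophage genes 3 were lower and 0 higher (median -1.23, camera adjusted p = 0.403, adjusted p = 0.475 with an estimated correlation, 0.0265 in fry). Mitochondrial transcripts took 0.304% to 0.423% of the counts in VmSC4 and 0.0722% to 0.167% in VmSC5.

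After 8 days of adipogenic culture both populations carried a full adipocyte program. Adipoq, the adipocyte hormone adiponectin, rose from 0.916 ± 1.22 to 5263 ± 378 CPM in VmSC4 and from 0.541 ± 0.0873 to 5131 ± 210 CPM in VmSC5. Fabp4 reached 12912 ± 559 and 13106 ± 640 CPM, log2 rises of 7.23 ± 0.16 and 7.66 ± 0.17. Pparg rose by 3.21 ± 0.19 and 3.31 ± 0.20, to 121 ± 1.38 and 135 ± 5.08 CPM (edgeR adjusted p = 1.2e-12 and 7.4e-13). All 31 adipocyte genes tested rose in VmSC4 and in VmSC5 (camera with an estimated correlation, adjusted p = 8.55e-05 and 6.75e-05). The brown-fat gene Ucp1, a mitochondrial uncoupler, was at 386 ± 22.1 CPM in cultured VmSC5 and 0 counts in fresh VmSC5, at least 3564-fold higher with a floor of 3 counts over the group.

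Metabolic genes moved with the adipocyte program. Of 22 lipid synthesis genes 20 rose and 1 fell in each population, with Dgat2, which makes triglycerides, up by 6.59 ± 0.15 and 6.61 ± 0.16. All 17 lipolysis genes and all 30 oxidative phosphorylation genes rose in both, among them Cycs, cytochrome c, by 5.63 ± 0.13 and 6.21 ± 0.14. Glycolysis and hypoxia genes had 19 of 22 higher in each (20 in VmSC4 adjusted over the list alone), and thermogenic genes 9 of 11. Cd34, a stem cell sialomucin, fell by -6.27 ± 0.21 and -6.26 ± 0.21, and Pi16 by -3.69 ± 0.43 and -4.62 ± 0.36 (edgeR adjusted p = 8.4e-07 and 4.6e-09). Dpp4 fell in VmSC5 by 2.05 on the log2 scale (SE 0.41, edgeR adjusted p = 7.4e-05), while in VmSC4, where it started at 2.09 CPM, the change of -0.44 ± 0.61 did not pass (edgeR adjusted p = 0.525). Icam1 fell by 0.96 and 1.90 on the log2 scale in VmSC4 and VmSC5 (edgeR adjusted p = 6.4e-05 and 1.7e-09). Of 18 progenitor genes 10 fell and 3 rose in VmSC4, and 14 fell and 0 rose in VmSC5 (camera with an estimated correlation, adjusted p = 0.0471 and 0.0153). Culture changed 9307 of 13221 genes in VmSC4 and 9389 in VmSC5. Of the 8067 genes called in both, 99.8% moved the same way, with 3776 up in both against 1407 from independent lists and 4273 down in both against 1917. Mitochondrial transcripts took 6.05% to 7.26% of the counts of the cultures and 0.0722% to 0.423% of those of the fresh cells. Preparation and depth also differed between fresh cells and cultures, so their effects cannot be told apart from that of culture.

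**Figure D2:**
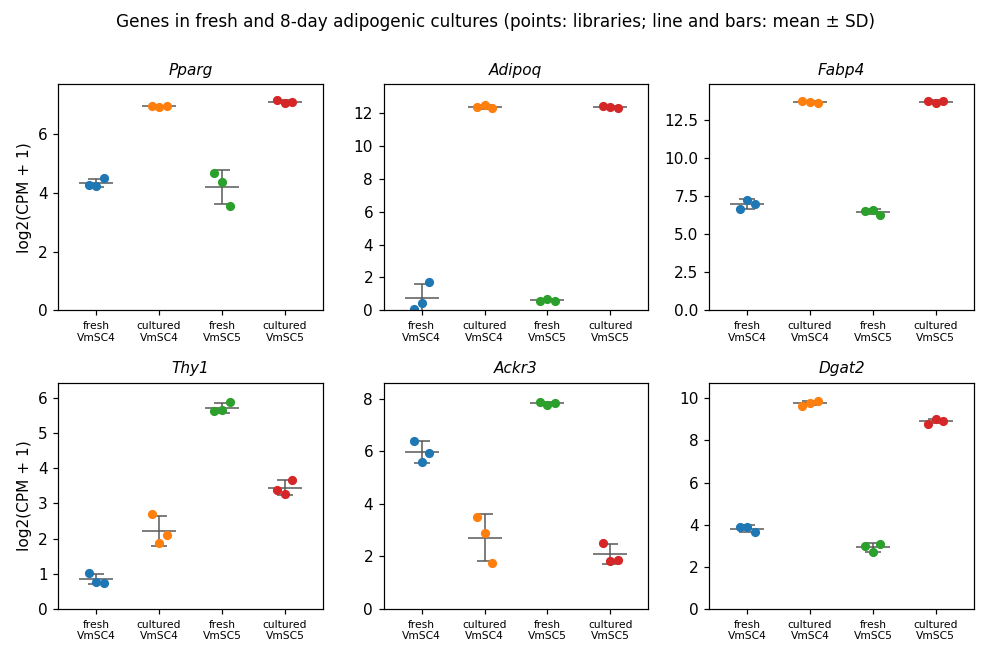
Expression as log2(CPM + 1) of 6 genes in fresh cells and after 8 days of adipogenic culture, with 1 point per library and the mean ± SD (n = 3 per group). Adipoq reached 5263 ± 378 CPM in VmSC4 and 5131 ± 210 CPM in VmSC5, and Thy1 was higher in fresh VmSC5 (51.4 ± 4.93 CPM) than in fresh VmSC4 (0.813 ± 0.196 CPM).

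Set side by side after culture, VmSC5 and VmSC4 differed little in their central adipocyte genes. Pparg differed by 0.13 ± 0.18, Adipoq by -0.07 ± 0.29 and Fabp4 by -0.01 ± 0.12 (edgeR adjusted p = 0.930, 0.993 and 1.0), and 1 of 31 adipocyte genes was lower in VmSC5 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00965, adjusted p = 0.202 with an estimated correlation). That lower gene was Dgat2, at 483 ± 37.5 against 868 ± 63.6 CPM (-0.88 ± 0.12, edgeR adjusted p = 0.000137), and it was also the 1 lipid synthesis gene of 22 to pass (7 lower adjusted over the list alone; camera adjusted p = 1.1e-06, adjusted p = 0.114 with an estimated correlation). Sfrp1, a secreted WNT antagonist, and Aldh1a3, which makes retinoic acid, were lower in VmSC5 by -2.15 ± 0.30 and -1.67 ± 0.19, and H2-Q10, a secreted MHC class I protein, was higher by 1.39 ± 0.19. Dpp4, Pi16 and Icam1 were at 3.11, 4.26 and 18.9 CPM in cultured VmSC5 (SD 2.01, 1.57 and 4.63) and did not pass (edgeR adjusted p = 0.561, 0.819 and 0.838). Of 25 type I interferon genes 0 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 2.00 (camera adjusted p = 4.2e-09, adjusted p = 0.356 with an estimated correlation), and of 26 interferon gamma genes 0 changed (1 rose adjusted over the list alone), with a median of 0.98 (camera adjusted p = 4.6e-09, adjusted p = 0.246 with an estimated correlation). Ifit1, named here after its values were seen, was at 264, 3.44 and 107 CPM in the VmSC5 libraries and 35.3, 3.84 and 12.1 CPM in those of VmSC4 (2.94 ± 1.16, edgeR adjusted p = 0.582). In all, 17 genes were higher and 28 lower. The count was 17 without VmSC4 replicate 2, 83 without VmSC4 replicate 3, and 27, 99 and 21 without VmSC5 replicates 1, 2 and 3. DESeq2 called 85.

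The difference between the responses to culture was tested as an interaction, in which 245 genes had a more positive and 134 a more negative change in VmSC5 than in VmSC4. Thy1 and Ackr3, higher in fresh VmSC5, had a more negative change in VmSC5 (-4.63 ± 0.48 and -2.84 ± 0.55, edgeR adjusted p = 1.5e-06 and 0.0101), and Aldh1a7, lower in fresh VmSC5, rose more (5.57 ± 0.38, edgeR adjusted p = 5.6e-07). Cidea, a lipid droplet protein of brown fat, rose more in VmSC5 by 6.90 ± 0.68 (edgeR adjusted p = 2.4e-05). Fresh VmSC5 held 2 Cidea counts and fresh VmSC4 188, a 73.4-fold lower level in VmSC5 (counting interval 20.1 to 611), while the difference of 1.13 ± 0.25 after culture did not pass in edgeR (adjusted p = 0.0688) and passed in DESeq2 (0.0048), in edgeR without the low-count filter (1.62e-07) and without VmSC4 culture replicate 3 (0.0251). The interaction did not pass for Pparg (0.11 ± 0.26), Adipoq (0.57 ± 0.94), Fabp4 (0.43 ± 0.18), Dpp4 (-1.61 ± 0.80), Pi16 (-0.93 ± 0.71) or Icam1 (-0.94 ± 0.27), with edgeR adjusted p values of 0.889, 0.821, 0.199, 0.297, 0.551 and 0.0546. Of 18 progenitor genes 2 had a more negative change in VmSC5 (4 adjusted over the list alone; camera adjusted p = 0.00234, adjusted p = 0.0775 with an estimated correlation). The Ackr3 call ended without VmSC4 culture replicate 2 (edgeR adjusted p = 0.0646), Icam1 passed without fresh VmSC4 replicate 3 or fresh VmSC5 replicate 1 (0.0438 and 0.0266), and Fabp4 passed without fresh VmSC4 replicate 1 (0.0348). Icam1 also passed with RLE scaling (0.0421), in DESeq2 (0.0295) and without the low-count filter (0.0411), and Fabp4 without that filter (0.0409). Without fresh VmSC5 replicates 1 and 2 the interaction count was 661 and 229, without culture VmSC4 replicates 1 and 2 it was 235 and 155, and without culture VmSC5 replicates 1 and 3 it was 176 and 161.

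The transfer asked whether VmSC4 turn into VmSC5 in a recipient mouse. Transferred VmSC4 that were recovered as VmSC5 carried more progenitor transcripts than those recovered as VmSC4, though the labels do not give the gates that parted them. Dpp4 was at 73.0 ± 6.36 against 29.9 ± 4.05 CPM (log2 fold change 1.37 ± 0.18, edgeR adjusted p = 0.000109) and Ackr3 at 303 ± 13.0 against 86.5 ± 8.82 CPM (1.89 ± 0.15, edgeR adjusted p = 4.4e-08). Thy1, which is not in the progenitor list, was at 26.1 ± 4.5 against 1.18 ± 0.303 CPM (4.62 ± 0.31, edgeR adjusted p = 6.2e-10). Efhd1, a mitochondrial calcium sensor, and the guidance factor Sema3c, both progenitor markers, rose by 2.50 ± 0.29 and 1.41 ± 0.17. Dpp4 in VmSC4-derived VmSC4, at 29.9 CPM, was already above its level in fresh VmSC5, so its level alone does not mark VmSC5. Of 20 progenitor genes 10 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.93, a camera adjusted p of 6.6e-29 and an adjusted p of 0.000142 with an estimated correlation. Cmklr1, the receptor of the adipokine chemerin, was among the largest falls (-1.38 ± 0.22, edgeR adjusted p = 0.000885). Pi16, Icam1, Pparg and Fabp4 did not pass (edgeR adjusted p = 0.112, 0.275, 0.699 and 0.991), at 425 ± 58.0, 241 ± 19.6, 4.79 ± 1.32 and 23.4 ± 5.46 CPM in VmSC4-derived VmSC5. Pi16 passed in DESeq2 (log2 fold change 0.68, adjusted p = 0.0327), and in edgeR without the low-count filter (4.1e-05) or with the 2 groups alone (9.66e-05). Proliferation genes had 0 of 22 called (1 higher adjusted over the list alone; camera adjusted p = 0.00146, adjusted p = 0.670 with an estimated correlation).

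In all, 104 genes were higher and 143 lower in VmSC4-derived VmSC5 than in VmSC4-derived VmSC4. The count was 39 and 119 without VmSC4-derived VmSC4 replicates 2 and 3, and 59 and 49 without VmSC4-derived VmSC5 replicates 2 and 3, and DESeq2 called 458. It was higher still with the 2 groups alone, as given below. Of the 257 genes more than 2-fold higher in fresh VmSC5, 19 rose and 6 fell (60.3% above 0; camera adjusted p = 0.00142, adjusted p = 0.246 with an estimated correlation), and of the 608 lower ones, 14 fell and 1 rose (camera adjusted p = 0.00358, adjusted p = 0.242 with an estimated correlation). With no minimum fold change, the 1532 lower genes gave a camera adjusted p of 0.512. A score of these genes was 0.344 ± 0.00336 in VmSC4-derived VmSC5 and 0.0481 ± 0.0992 in VmSC4-derived VmSC4, against 0.572 ± 0.058 in VmSC5-derived VmSC5 (n = 2). Fresh VmSC4 and VmSC5 scored -0.879 ± 0.225 and 1.72 ± 0.276, and the genes of the score were chosen on those same fresh libraries. An exact permutation test of the difference of 0.296 between VmSC4-derived VmSC5 and VmSC4-derived VmSC4 gave p = 0.1 (two-sided), the smallest that 3 against 3 libraries allow. Across genes, which are not independent replicates, the fold changes of the fresh and the transferred comparison correlated with a Pearson's r of 0.107.

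VmSC4-derived VmSC5 were also set against VmSC5-derived VmSC5 (n = 2), the cells labelled VmSC5 both before and after transfer. Ackr3 was lower in VmSC4-derived VmSC5, at 303 ± 13.0 against 672 ± 95.3 CPM (-1.07 ± 0.16, edgeR adjusted p = 0.000391), while Dpp4, at 73.0 ± 6.36 against 117 ± 24.7 CPM, did not pass (edgeR adjusted p = 0.113) except with the 2 groups alone (-0.61, edgeR adjusted p = 0.00768). Of 20 progenitor genes 5 were lower and 0 higher (8 and 0 adjusted over the list alone; camera with an estimated correlation, adjusted p = 0.0194). Matrix genes went the other way: 4 of 30 were higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 1.3e-10, adjusted p = 0.172 with an estimated correlation). Col1a2, a chain of type I collagen, was at 23075 ± 448 against 12132 ± 536 CPM (1.00 ± 0.14, edgeR adjusted p = 0.00014), and Lrrc15, a marker of matrix-secreting fibroblasts, at 27.0 ± 6.02 against 0.758 ± 0.503 CPM. Has1, a hyaluronan synthase, and Smpd3, a sphingomyelinase, were lower by -1.51 ± 0.14 and -1.60 ± 0.14. Pi16, Icam1, Pparg and Fabp4 did not pass (edgeR adjusted p = 0.687, 0.185, 0.294 and 0.876), though Icam1 passed with the 2 groups alone (0.44, edgeR adjusted p = 0.0101). In all, 73 genes were higher and 87 lower; the count lay between 31, without VmSC5-derived VmSC5 replicate 2, and 84, without its replicate 1, and was 74, 74 and 82 without VmSC4-derived VmSC5 replicates 1, 2 and 3. DESeq2 called 266.

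**Figure D3:**
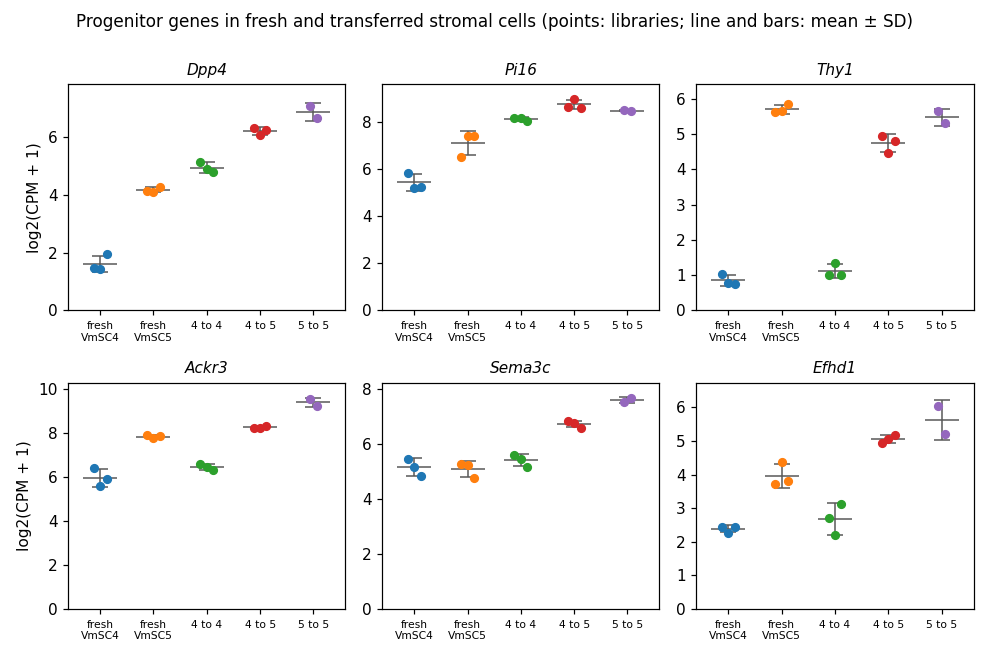
Expression as log2(CPM + 1) of 6 genes in fresh VmSC4, fresh VmSC5 and the transferred cells (4 to 4, 4 to 5 and 5 to 5 name the population before and after transfer), with 1 point per library and the mean ± SD (n = 3, and n = 2 for 5 to 5). Dpp4, Pi16, Ackr3, Sema3c and Efhd1 are in the progenitor list, and Thy1 was named for its large rise. Ackr3 was at 86.5 ± 8.82 CPM in VmSC4-derived VmSC4, 303 ± 13.0 in VmSC4-derived VmSC5 and 672 ± 95.3 in VmSC5-derived VmSC5.

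Recovered cells were also compared with fresh cells of their own population. Il6, an inflammatory cytokine, rose by 3.86 ± 0.28 in VmSC4-derived VmSC4 and 6.94 ± 0.37 in VmSC5-derived VmSC5, and the stress factor Atf3 by 2.16 ± 0.25 and 5.04 ± 0.29. Fn1 rose by 2.33 ± 0.12 and 1.44 ± 0.12, and Col1a2 by 2.02 ± 0.12 and 0.96 ± 0.13. Dpp4 rose by 3.85 ± 0.22 and 2.71 ± 0.19, Pi16 by 2.71 ± 0.23 and 1.26 ± 0.23, and Icam1 by 1.76 ± 0.13 and 0.94 ± 0.14. Pparg fell by 1.57 and 0.97 on the log2 scale (SE 0.32 and 0.33, edgeR adjusted p = 0.000239 and 0.0180), and Fabp4 by 2.30 and 1.61 (edgeR adjusted p = 2.9e-05 and 0.0013). The VmSC5 call of Pparg ended without fresh VmSC5 replicate 1 or 2 or either VmSC5-derived VmSC5 replicate, with adjusted p values from 0.0507 to 0.112.

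Progenitor genes rose in both recovered populations, 14 of 20 with 1 falling in VmSC4 and 17 with 0 falling in VmSC5 (camera with an estimated correlation, adjusted p = 0.0411 and 0.00826). Inflammatory genes had 9 and 12 of 24 higher and 3 and 1 lower (camera adjusted p = 0.000318 and 2.19e-05, adjusted p = 0.136 and 0.252 with an estimated correlation). Dissociation stress genes had 12 and 15 of 20 higher (adjusted p = 0.394 and 0.300 with an estimated correlation), and matrix genes 24 and 16 of 30 (27 and 16 adjusted over the list alone; adjusted p = 0.0546 and 0.302). Oxidative phosphorylation genes had 26 and 16 of 29 lower, among them Ndufb8, a subunit of complex I, by -1.30 ± 0.13 and -1.01 ± 0.15 (adjusted p = 0.109 and 0.389 with an estimated correlation). Markers of other cell types also changed. Endothelial genes had 2 and 6 of 9 higher and 0 lower (medians 0.49 and 2.14, camera adjusted p = 0.440 and 0.159, adjusted p = 0.710 and 0.528 with an estimated correlation, and 0.154 and 0.0119 in fry). Ighm, the heavy chain of IgM, had 4202 counts in fresh VmSC4, 3960 of them in replicate 2, and 0 in VmSC4-derived VmSC4, at least 435-fold lower with a floor of 3 counts over the group. Its call (edgeR adjusted p = 0.0286) ended without any 1 VmSC4-derived VmSC4 library, with adjusted p values from 0.0534 to 0.0700, without the low-count filter (0.0734) and with the 2 groups alone (0.288). In all, 6432 and 6466 of 13947 genes changed. Of the 4300 called in both, 97.7% moved the same way. Fresh and transferred libraries differed in depth and in mitochondrial share (0.0722% to 0.423% and 0.670% to 1.04%), and the transferred cells also passed through a recipient mouse.

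Floating cells of VAT were compared to ask what Treg depletion changes in adipocytes. In DTR+ mice, some genes induced by interferon gamma rose. Igtp, an interferon-inducible GTPase, was at 293 ± 12.2 CPM in DTR+ and 17.8 ± 0.828 in DTR- (log2 fold change 4.52 ± 0.68, edgeR adjusted p = 0.0031), H2-T23, a nonclassical MHC class I molecule, at 114 ± 24.7 against 5.90 ± 0.950 CPM, and Psmb8, an immunoproteasome subunit, at 454 ± 139 against 82.4 ± 6.22 CPM (3.00 ± 0.68, edgeR adjusted p = 0.0205). Of 30 interferon gamma and antigen presentation genes 7 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.76 and a camera adjusted p of 1.1e-12 (adjusted p = 0.225 with an estimated correlation). Type I interferon genes had 3 of 26 higher (7 adjusted over the list alone; camera adjusted p = 0.000105, adjusted p = 0.262 with an estimated correlation). Ccl2, a monocyte chemokine, and Cd14, a myeloid receptor, rose by 3.10 ± 0.71 and 3.30 ± 0.69.

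Some transcripts of some other cell types of the tissue fell in the same libraries. Cdh5, the endothelial cadherin, was at 3.62 ± 2.81 CPM in DTR+ and 111 ± 29.4 in DTR- (-4.63 ± 0.71, edgeR adjusted p = 0.00326), Col1a1, a chain of type I collagen, at 4.62 ± 5.18 against 174 ± 153 CPM, and Acta2, smooth muscle actin, at 5.59 ± 0.586 against 87.2 ± 15.6 CPM. Of 14 endothelial genes 11 fell (14 adjusted over the list alone), with a median of -3.37 (camera adjusted p = 1.6e-19, adjusted p = 0.225 with an estimated correlation). Falling members numbered 10 of 25 for matrix, 5 of 12 for progenitor, 4 of 10 for pericyte, 3 of 12 for fibroblast and 2 of 11 for mesothelial genes (15, 9, 5, 5 and 3 adjusted over the list alone). Of 20 macrophage genes 1 rose and 0 fell (1 and 3 adjusted over the list alone), and of 5 erythrocyte genes 0 changed (0 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.000477, adjusted p = 0.336 with an estimated correlation). Of 2 neutrophil genes, 4 B cell genes and 4 genes of a sex check, 0 changed (1 neutrophil gene fell adjusted over the list alone). Mest, an imprinted gene of growing adipocytes, fell by 5.20 on the log2 scale.

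Adipocyte genes themselves did not pass in the floating cells. Adipoq stood at 9387 ± 3919 CPM in DTR+ and 6316 ± 1506 in DTR- (edgeR adjusted p = 0.436), Fabp4 at 7233 ± 2274 and 4699 ± 1146 (edgeR adjusted p = 0.413), and Icam1 at 2.95 ± 2.63 and 3.65 ± 0.151 (edgeR adjusted p = 0.987). Pparg was at 241 CPM in DTR+ replicate 2, 12.3 CPM in DTR+ replicate 3, and 191 and 242 CPM in the DTR- libraries (edgeR adjusted p = 0.697). All 31 adipocyte genes tested, 22 lipid synthesis genes and 16 lipolysis genes held 0 calls by edgeR over all genes (0 rose and 1 fell in the adipocyte list adjusted over the list alone). DTR+ replicate 3 stood apart: it had 15351 genes detected, against 17034 to 17903 in the others, and gave 11.7% of its counts to Car3. Across genes, log2 fold change correlated with transcript length (Spearman's rho -0.476, and -0.261 without DTR+ replicate 3), and genes are not independent replicates. The mitochondrial share was 1.86% to 2.10% in DTR- and 2.54% to 2.97% in DTR+. Of the genes more than 2-fold up with adipogenic culture of VmSC5, 2975 were tested. Of these 20 rose and 23 fell (camera adjusted p = 1.3e-08, up). Of those down with culture, 2818 were tested, and 4 rose and 114 fell (3.4e-13, down). Of those up with OSM, 806 were tested, and 7 rose and 69 fell (6.3e-07, down). Of those down with OSM, 916 were tested, and 11 rose and 18 fell (0.0241, up). With an estimated correlation these were 0.242, 0.242, 0.158 and 0.242. In all, 58 genes were higher and 229 lower among 11803 tested, 1940 had an unadjusted p under 0.05, and DESeq2 called 545.

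The count in the floating cells rested on single libraries, and each run without 1 of them left that arm with 1 library, assumed to vary like the other pair: 26 genes were called without DTR- replicate 2, 6 without DTR- replicate 3, 5370 without DTR+ replicate 2 and 918 without DTR+ replicate 3. Without DTR+ replicate 3, the list median of log2 fold change was 1.92 for interferon gamma, -3.33 for endothelial and -1.01 for macrophage genes. It was 0.147 for adipocyte, 0.436 for lipid synthesis and 0.132 for lipolysis genes. Such medians do not show that single members of these lists were unchanged. The calls of Igtp, H2-T23, Psmb8, Ccl2, Cd14 and Acta2 ended without DTR- replicate 2 or 3 (edgeR adjusted p from 0.225 to 1.0), and those of Cdh5 and Col1a1 without DTR- replicate 3 (0.127 and 0.328). The fold changes moved less: without DTR- replicates 2 and 3 they were 4.54 and 4.50 for Igtp, 4.70 and 4.89 for H2-T23, and 3.15 and 2.86 for Psmb8. Pparg, Adipoq and Fabp4 passed without DTR+ replicate 2, where only DTR+ replicate 3 stood for DTR+ (edgeR adjusted p = 2.4e-11, 0.00204 and 0.00195), and Adipoq and Fabp4 with all groups in 1 fit (0.0469 and 0.00535). Simulated data of this comparison recovered 0% of genes changed 2-fold and 5% of those changed 4-fold.

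**Figure D4:**
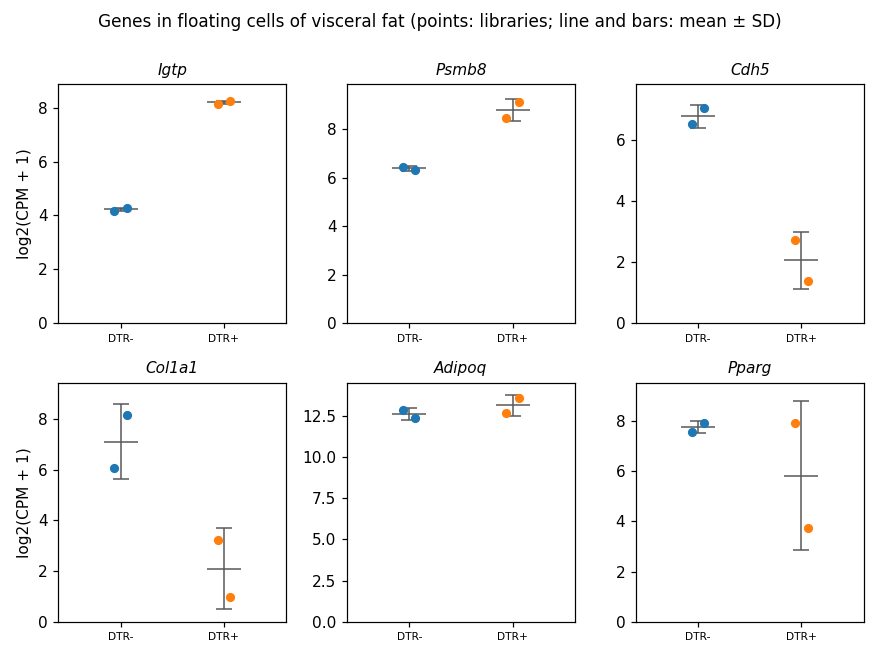
Expression as log2(CPM + 1) of 6 genes in floating cells of toxin-treated DTR- and DTR+ mice, with 1 point per library and the mean ± SD (n = 2 each). Igtp was at 17.8 ± 0.828 CPM in DTR- and 293 ± 12.2 in DTR+, and Pparg of the DTR+ libraries was at 241 and 12.3 CPM.

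The cultures with Treg asked whether Treg products act on VmSC5 directly. Interferon-response genes rose most. Igtp went from 6.29 ± 1.47 to 1328 ± 25.8 CPM (log2 fold change 7.76 ± 0.09, edgeR adjusted p = 2e-37), Irf7, an interferon regulatory factor, from 5.96 ± 0.652 to 1500.4 ± 35.8 CPM (7.99 ± 0.09), and Psmb8 from 17.9 ± 1.65 to 831 ± 37.2 CPM. Gbp10, a guanylate-binding protein, had 0 counts without Treg and was at least 975-fold higher with it, with a floor of 3 counts over the group. All 27 type I interferon genes and all 30 interferon gamma genes tested rose (camera with an estimated correlation, adjusted p = 0.0189 and 0.0077). Of 24 inflammatory genes 20 rose and 0 fell, among them the monocyte chemokine Ccl7 by 6.29 ± 0.12 (camera adjusted p = 7.7e-26, adjusted p = 0.0674 with an estimated correlation). Of 34 genes of the OSM-STAT3 response 33 rose (camera with an estimated correlation, adjusted p = 0.0315). Socs3, the feedback inhibitor of STAT3, was at 67.8 ± 7.3 against 12.8 ± 1.69 CPM (2.41 ± 0.12), and the OSM receptor subunits Osmr and Il6st rose by 1.27 ± 0.08 and 0.85 ± 0.07. Serpina3n, an acute phase protease inhibitor, rose by 2.65 ± 0.06.

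Adipocyte genes fell with Treg. Adipoq was at 1386 ± 93.0 against 3489 ± 165 CPM (-1.32 ± 0.06, edgeR adjusted p = 8.6e-21), and Cidec, a lipid droplet protein, at 1382 ± 69.8 against 3779 ± 47.8 CPM. Of 29 adipocyte genes 26 fell and 1 rose (camera adjusted p = 2.5e-12, adjusted p = 0.244 with an estimated correlation), of 22 lipid synthesis genes 21 fell, with Scd1, a fatty acid desaturase, down by -1.40 ± 0.05 (adjusted p = 0.0701 with an estimated correlation), and all 30 oxidative phosphorylation genes fell (adjusted p = 0.315 with an estimated correlation). The mitochondrial share of the counts was 4.13% to 4.42% without Treg and 1.78% to 2.03% with it. Fabp4 fell less, by -0.37 ± 0.06 (edgeR adjusted p = 2.1e-06), and Pparg least, at 70.1 ± 5.16 against 82.4 ± 4.29 CPM (-0.22 ± 0.08, edgeR adjusted p = 0.0206). The Pparg call ended without the no-Treg replicate 1 or the Treg replicate 1 or 3, with adjusted p values of 0.115, 0.0761 and 0.0777, in DESeq2 (0.0739) and without the low-count filter (0.0559). Dpp4, Pi16 and Icam1 rose by 0.69 ± 0.12, 1.91 ± 0.26 and 1.85 ± 0.12 (edgeR adjusted p = 1.03e-05, 0.00101 and 5.02e-16). With all groups of the series in 1 fit the calls of Pparg, Fabp4 and Dpp4 ended (edgeR adjusted p = 0.809, 0.374 and 0.155). Of the 3385 genes more than 2-fold up with adipogenic culture of VmSC5, 3119 were tested here, and 1358 of these fell and 450 rose with Treg (camera adjusted p = 6.2e-06, adjusted p = 0.195 with an estimated correlation). In all, 2768 genes rose and 2589 fell among 12356 tested.

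The OSM cultures asked what the cytokine does to the same cells. OSM induced its own pathway: Socs3 was at 748 ± 77.0 CPM against 32.4 ± 5.42 in PBS (4.63 ± 0.12, edgeR adjusted p = 2.6e-34), Osmr at 1009 ± 10.9 against 170 ± 7.92 CPM, and Il6st rose by 2.58 ± 0.09. Il4ra, the interleukin-4 receptor, and Il33, an alarmin of stromal cells, rose by 4.45 ± 0.10 and 6.27 ± 0.16. Of 33 OSM-STAT3 genes 27 rose and 2 fell (28 and 2 adjusted over the list alone), and of 21 inflammatory genes 18 rose and 1 fell (19 and 1 adjusted over the list alone; camera with an estimated correlation, adjusted p = 0.00986 and 0.00851). The adipocyte program was lower: Adipoq was at 2.12 ± 1.92 against 271 ± 48.2 CPM (-6.86 ± 0.27, edgeR adjusted p = 1.2e-19), Pparg at 18.9 ± 8.79 against 146 ± 16.9 CPM (-2.87 ± 0.19, edgeR adjusted p = 7.4e-17), and Fabp4 fell by 3.01 on the log2 scale (edgeR adjusted p = 1.8e-10). Lpl, the lipoprotein lipase, and Lipe, the hormone-sensitive lipase, fell by 3.68 and 4.83 on the log2 scale. All 25 adipocyte genes and all 16 lipolysis genes tested fell, with adjusted p = 0.00851 and 0.00986 with an estimated correlation in camera, and 18 of 22 lipid synthesis genes fell with 1 rising.

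OSM also changed stromal genes. Of 30 matrix genes 23 rose and 5 fell (camera with an estimated correlation, adjusted p = 0.0287), with Col3a1, type III collagen, at 42881 ± 4842 against 6847 ± 236 CPM, and of 10 pericyte and smooth muscle genes 7 rose (8 adjusted over the list alone), with Acta2 up by 2.58 ± 0.10. Markers of other cell types moved too. Of 7 mesothelial genes 5 fell and 1 rose (median -3.08, camera adjusted p = 0.0756, not passing with an estimated correlation either, 0.0069 in fry), with Upk1b, a uroplakin, at 132 counts in PBS and 2 in OSM (ratio 55.8, counting interval 15.1 to 465) and Upk3b at 72 and 0, at least 20.3-fold lower with a floor of 3 counts over the group. With Treg 5 of 10 mesothelial genes rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.354, adjusted p = 0.635 with an estimated correlation, 0.0116 in fry). Of 10 endothelial genes 9 rose with OSM (camera adjusted p = 0.0015, adjusted p = 0.0815 with an estimated correlation). Anti-adipogenic regulators had 7 of 11 higher and 2 lower (camera with an estimated correlation, adjusted p = 0.0455). Pi16 rose to 353 ± 61.1 from 20.6 ± 7.9 CPM (4.12 ± 0.18), Icam1 rose by 1.44 ± 0.13, and Dpp4 fell, to 7.29 ± 2.92 from 33.7 ± 5.06 CPM (-2.04 ± 0.30, edgeR adjusted p = 1.4e-07). Interferon gamma genes had 8 of 18 lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.0261, adjusted p = 0.199 with an estimated correlation), with B2m, the light chain of MHC class I, at 265 ± 10.2 against 947 ± 26.8 CPM and Iigp1, an interferon-inducible GTPase, down by 2.65 on the log2 scale. Of the 3385 genes more than 2-fold up and 3891 down with adipogenic culture of VmSC5, 2549 and 2487 were tested with OSM, where 1239 of the former fell and 293 rose, and 908 of the latter rose and 249 fell (camera with an estimated correlation, adjusted p = 0.0227 for both). In all, 2245 genes rose and 2255 fell among 9825 tested, and the mitochondrial share was 2.40% to 2.92% in PBS and 1.53% to 1.64% in OSM.

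**Figure D5:**
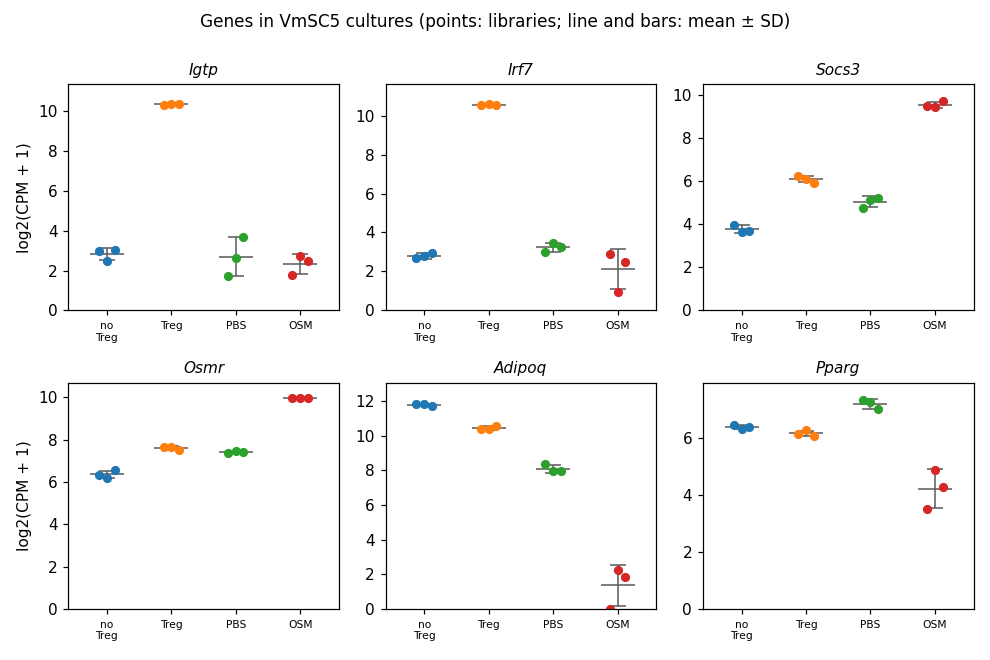
Expression as log2(CPM + 1) of 6 genes in VmSC5 cultures without Treg, with Treg, with PBS and with OSM, with 1 point per library and the mean ± SD (n = 3 each). Igtp was at 6.29 ± 1.47 CPM without Treg and 1328 ± 25.8 with it, and Adipoq fell from 271 ± 48.2 CPM in PBS to 2.12 ± 1.92 in OSM.

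Both treatments were compared through the difference between their responses, each against its own control. Of the 9733 genes tested in both, 1086 rose in both against 510 from independent lists, 1151 fell in both against 513, and 82.9% of the 2699 called in both moved the same way. Across genes, which are not independent replicates, the fold changes correlated with a Pearson's r of 0.405 and a Spearman's rho of 0.434. Of the 1065 genes more than 2-fold up and 948 down with OSM, 983 and 946 were tested with Treg, where 572 of the former rose and 61 fell, and 607 of the latter fell and 115 rose (camera adjusted p = 1.9e-14 and 3.3e-11, adjusted p = 0.103 with an estimated correlation for both). The interferon genes set the responses apart: of 30 interferon gamma genes 27 were lower in the OSM response, and of 27 type I genes 26 (camera with an estimated correlation, adjusted p = 0.000565 and 0.0118), with Iigp1 at -8.31 ± 0.17 and B2m at -4.30 ± 0.10. OSM lowered adipocyte genes further, Adipoq by -5.53 ± 0.34, Pparg by -2.61 ± 0.20 and Fabp4 by -2.60 ± 0.17, and 24 of 28 genes of that list were lower with 1 higher (25 and 1 adjusted over the list alone). It raised Socs3, Osmr and Il6st further, by 2.26 ± 0.18, 1.44 ± 0.11 and 1.77 ± 0.12 (edgeR adjusted p = 1.2e-13, 2.2e-14 and 6.3e-16). Dpp4 went apart by -2.69 ± 0.30 and Pi16 by 2.25 ± 0.45, while Icam1 did not pass (-0.37 ± 0.18, edgeR adjusted p = 0.109) except without OSM replicate 3 (0.0428). In all, 1817 genes had a more positive and 2124 a more negative change with OSM than with Treg, and the control levels differed between the experiments, with Adipoq at 3489 ± 165 CPM without Treg and 271 ± 48.2 in PBS. A larger fold change from a different control level cannot be read as a stronger action of OSM.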

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

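Of the tests in this part, those on Treg RNA, on a common loss of cells, on DTR+ replicate 3 and on admixed cells were chosen only after the result was seen, and the others were written down earlier. The rise of interferon-response genes in VmSC5 with Treg was weighed against RNA carried over from Treg cells. Of the 57 risen interferon genes, 44 stood above the highest Treg library in all treated wells, while Cd3e, at 0 counts in the treated cultures, allows a Treg share of 0.0198% at most and Ptprc, at 2.14 CPM with Treg and 1.53 without, would need about 0.0943% if all its counts came from Treg cells. With all 6 libraries thinned to 4648878 counts, 57 of the 57 still rose in edgeR, so greater depth was not needed for the rise. The 44 of 57 genes above Treg level speak to carried-over RNA only, and do not show whether an interferon was released or by which cells. An interferon released by Treg cells may act on VmSC5. Blocking the interferon receptors in these cultures would test whether an interferon acts, not where it comes from.

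The fall of endothelial and other cell type markers in floating cells of DTR+ mice could come from the makeup of the floating fraction as well as from the tissue. The list medians of log2 fold change ran from -3.37 for endothelial to -0.86 for fibroblast genes, and a permutation rank test of the 5 lists, which takes genes as independent, gave p = 0.0011. Members were then limited to genes with a mean CPM in the adipogenic cultures far below that in DTR- floating cells. That choice uses the DTR- arm of this comparison and can favour a fall. Their quartiles were -3.99 and -2.57 for endothelial and -1.88 and -0.98 for macrophage genes. Mesothelial quartiles, at -3.44 and -2.64, overlapped the endothelial ones, but not without DTR+ replicate 3 (-2.68 and -1.82). Without that library the endothelial and macrophage quartiles stayed apart (-3.49 and -2.93, -1.66 and -0.78). With DTR+ replicate 3 alone they overlapped (-5.27 and -2.61, -3.06 and -0.78), so a single common loss of all cell types stays open. Removing the trend on transcript length and GC moved the endothelial median from -3.37 to -3.07 (upper quartile -2.73), and without DTR+ replicate 3 it was -3.33 with 14 members falling. Different losses per cell type, a real loss of vessels, and changes in adipocytes themselves may each produce unequal medians (permutation p = 0.0011), and counting endothelial cells in sections of the same fat pads would help to separate them.

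The progenitor genes called higher in VmSC4-derived VmSC5 lay between the other transferred groups, which conversion, an admixture of the recipients' own VmSC5 and a progenitor marker in the sorting gate might all give. Over the risen progenitor genes the median fraction of the way from VmSC4-derived VmSC4 to VmSC5-derived VmSC5 was 0.432, from 0.324 to 0.600. These genes were picked on the same libraries, so a level above VmSC4-derived VmSC4 was fixed by that choice. The size of the fraction may be too large for that reason, and the other list genes are not in it. The recipients' own VmSC5 were not sequenced and the gates are not given, so that fraction cannot tell the explanations apart. Under RLE scaling 9 of the 10 genes still rose in edgeR, so the choice of scaling was not the source. A donor marker read in each sorted cell would test admixture, and the gate was not tested.

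The interaction of population and adipogenic culture held 379 called genes, and 3 of 100 regroupings of the libraries, the real one included, called as many, with 834 in the highest other. Among its calls were Cidea at 6.90, Aldh1a7 at 5.57, Thy1 at -4.63 and Ackr3 at -2.84, all of which already differed between fresh VmSC5 and VmSC4. The difference between the OSM and the Treg response held 3941 called genes, and 4 of 100 regroupings called as many, with 7779 in the highest other. These regroupings exchanged population or experiment labels within each condition. A regrouping that exchanges all labels within a single condition tests the mean difference between populations or experiments, not the difference between responses. Such regroupings can call more genes than the real one, so the shares above do not measure chance. Interferon genes led the difference between the OSM and the Treg response, with Iigp1 at -8.31 and B2m at -4.30. The adipocyte genes Adipoq, Pparg and Fabp4 went further down with OSM, by -5.53, -2.61 and -2.60, from control levels that differed between the experiments. The OSM pathway genes Socs3, Il6st and Osmr went further up, by 2.26, 1.77 and 1.44. The progenitor genes split, Dpp4 at -2.69 and Pi16 at 2.25.

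For 9 comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05, and in each 1 of 10 splits, the real one, called the most genes. The real and the highest other counts were 2566 and 1 for fresh VmSC5 against VmSC4, 9307 and 0 for culture of VmSC4, 9389 and 0 for culture of VmSC5, and 45 and 24 for VmSC5 against VmSC4 after culture. They were 247 and 0 for VmSC4-derived VmSC5 against VmSC4-derived VmSC4, 6432 and 0 for VmSC4-derived VmSC4 against fresh VmSC4, 5357 and 0 for Treg, 4500 and 0 for OSM, and 6 and 0 for Osm KO against WT Treg cells.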

How the results depend on the processing

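The crossed replicate block of the floating cells and the list counts without doubted libraries were chosen only after the result was seen, and every other alternative before. RLE scaling left all 14 counts of changed genes within 1.5 times. DESeq2 moved 5 of 14 counts: VmSC5 against VmSC4 after culture from 45 to 85, VmSC4-derived VmSC5 against VmSC4-derived VmSC4 from 247 to 458 and against VmSC5-derived VmSC5 from 160 to 266, the floating cells from 287 to 545, and the Treg cells from 6 to 62. Without the low-count filter the first 3 of these were 167, 450 and 314, the Treg cells 199, and the interaction of population and culture 644. The cause of these shifts was not tested.

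The choice of groups in the fit, which also changes which genes are tested, moved counts too, and the cause was not tested. With the 2 compared groups alone the counts were 215 for VmSC5 against VmSC4 after culture, 893 for VmSC4-derived VmSC5 against VmSC4-derived VmSC4 and 529 against VmSC5-derived VmSC5. With all 15 groups in 1 fit they were 146 for the interaction of population and culture, 5228 for the floating cells, 2005 for Treg, 1623 for the difference between the OSM and the Treg response and 460 for the Treg cells. The OSM count stayed within 1.5 times.

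Leaving out single libraries moved 29 counts beyond 1.5 times and left 63 within. They ran from 17 to 99 for VmSC5 against VmSC4 after culture, from 155 to 661 for the interaction of population and culture, from 39 to 166 for VmSC4-derived VmSC5 against VmSC4-derived VmSC4 and from 31 to 84 against VmSC5-derived VmSC5. For the floating cells they ran from 6 to 5370 and for the Treg cells from 0 to 586. The loss of a library lowers the number of samples, and no other cause was tested.

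The labels do not say that replicate numbers pair the samples. After removal of group means, libraries of the same number correlated at r from -0.413 to 0.0957 over the 12 comparisons of 2 groups. For VmSC5 against VmSC4 after culture all 3 libraries correlated best with their own number, at r from 0.0329 to 0.0957. A block on that number left 13 of 14 counts within 1.5 times and gave 111 for the floating cells, and a block with crossed numbers gave 1055 there. With the block Icam1 passed in the interaction of population and culture (edgeR adjusted p = 0.0421) and Cidea in VmSC5 against VmSC4 after culture (0.0126), and the calls of Psmb8, Ccl2 and Cd14 in the floating cells (0.189, 0.141 and 0.0845), Lpcat2 in the Treg cells (0.0936) and Ighm in VmSC4-derived VmSC4 against fresh VmSC4 (0.0597) ended.

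Named genes kept their label in most settings, and all those whose sign turned had not passed. Pparg in fresh VmSC5 against VmSC4 was -0.036 with the block and from -0.23 to 0.32 with libraries left out. Fabp4 in VmSC5 against VmSC4 after culture was 0.019 with the 2 groups alone and from -0.065 to 0.011 with libraries left out. In the interaction of population and culture Pparg ran from -0.14 to 0.36 and Adipoq from -1.42 to 1.15. In VmSC4-derived VmSC5 against VmSC4-derived VmSC4 Pparg ran from -0.633 to 0.045 and Fabp4 from -0.27 to 0.48, with 0.026 under the block, and against VmSC5-derived VmSC5 Fabp4 ran from -0.62 to 0.23. In the floating cells Icam1 was 0.017 with RLE, 0.008 with DESeq2 and from -0.94 to 0.49 with libraries left out, and Pparg ran from -3.34 to 0.25 there. Foxp3 in the Treg cells ran from -0.40 to 0.17. The cause of these turns was not tested.

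Over all named gene results, called or not, DESeq2 left the label of 150 unchanged, strengthened 4, weakened 1 and turned 1, and single libraries left out left 968 unchanged, weakened 30, strengthened 9 and turned 15. Ighm had no adjusted p in DESeq2. Of the list tests, called or not, an estimated correlation left 39 unchanged and weakened 32, fry left 52 unchanged, weakened 15 and strengthened 4, and RLE left all 71 unchanged. Of the tests of data-defined sets, an estimated correlation kept 3 and weakened 13, fry kept 7 and weakened 9, and no minimum fold change kept 15 and weakened 1, the genes lower in fresh VmSC5 in VmSC4-derived VmSC5 against VmSC4-derived VmSC4 (camera adjusted p = 0.512). Sets of 100 genes per direction kept 13, weakened 2 and turned 1, the genes up with culture of VmSC5 in VmSC4-derived VmSC5 against VmSC4-derived VmSC4 (camera adjusted p = 0.853), where few of the 100 were tested. The lowest library of the series, with 1072147 counts, was in the OSM and PBS cultures, where genes of low expression were filtered out.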

Other observations

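Other genes were looked at only after their values were seen. Ifng, which encodes interferon gamma, was at 8.11 to 16.7 CPM in the 6 Treg libraries and at 0 counts in all VmSC5 cultures, with or without Treg. Osm was at 0.696 CPM or less in every stromal and floating cell library, so among the sequenced cells only Treg cells reached higher levels. Immune cells other than Treg cells were not sequenced, so the source of Osm in the tissue is not shown.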
